A study of Mus musculus with 4 samples.

How the data were processed

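The series holds single-cell RNA-seq of mouse group 2 innate lymphoid cells (ILC2s), tissue-resident lymphocytes that secrete type 2 cytokines such as IL-5 and IL-13. Per the labels, there were 4 samples in 4 groups with 1 library each: ILC2s from the kidney of donor mice, ILC2s from the small intestinal lamina propria (SILP) of donor mice, and ILC2s from the SILP of recipients 2 and 8 weeks after they had been given kidney ILC2s. Donors were BALB/c mice with the IL-13fm reporter treated with recombinant IL-33. Recipients were BALB/c Rag2-/-Il2rg-/- mice, which make no lymphocytes of their own. Per the labels' protocols, kidneys were digested and enriched for CD45+ cells on magnetic beads, SILP cells were obtained by digestion and a Percoll gradient, and every sample was sorted for CD127 and the IL-13 reporter within lineage-negative CD45+ cells. Because the gate used the IL-13 reporter, the IL-7 receptor (CD127) and CD45, the transcripts Il13, Il7r and Ptprc are called gate genes here and their differences are no findings.

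Per the labels' protocols, libraries were made with a 10x Genomics Chromium 5-prime kit, which counts molecules by unique molecular identifier (UMI). Per the submitters' processing notes, Cell Ranger 4.0.0, Seurat (version not given in the sources used here) and the mm10 build were used. The deposited matrices hold whole-number UMI counts per gene and barcode, per the file headers, with no normalization. The lowest total per barcode was 486 to 500 UMIs. Gene symbols were taken from the deposited feature tables, and 32158 of 32285 identifiers (99.6%) were found in the GENCODE annotation of GRCm38, the assembly of mm10, from which coordinates are given (1-based).

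Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were retained: 8140 of 8390 in the kidney donor library, 6297 of 6498 in the SILP donor library, 9370 of 9683 at 2 weeks and 9277 of 10446 at 8 weeks. Cells were clustered (2000 variable genes, 30 principal components, 20 neighbours, Leiden at resolution 1, leidenalg 0.10.2) only to find cells of other types. A cluster was named by at least 3 markers of a list fixed before the data were examined. Each had to be at least 4-fold higher in the cluster and seen in at least 10% of its cells. Most ILC2 markers also had to be low in the cluster. A cluster with 3 dendritic cell markers but 0 low ILC2 markers was therefore not named, and its cells were kept. Cells of named other types were left out, which left 8131, 6210, 9363 and 9202 cells. Scrublet (in scanpy 1.11.5, expected rate 6%) called 0 doublets in each of the 4 libraries and so has not worked on these data. Doublets were therefore not removed, and the setting without them has no content.

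UMI counts of the analysed cells were summed per library and scaled to counts-per-million of the library total (CPM). A comparison took genes with at least 20 CPM in either library, and counted those whose ratio of (CPM + 1) was at least 2-fold. With 1 library per group there is no replicate spread and no test was made. Intervals on levels are exact Poisson intervals, those on folds are exact intervals from the conditional binomial distribution, and those on shares of cells are exact binomial (Clopper-Pearson) intervals, all at 95%. They cover counting error only, and neither the spread between mice nor that between library preparations. Those on levels and folds also leave out the spread between cells, and are too narrow where few cells hold many UMIs. At 2 weeks, for example, a single cell held 388 of 5415 Gzma UMIs. Folds are ratios of CPM. A gene with 0 UMIs in a library was set to 3 UMIs there and the fold is given as a lower bound. A single UMI was worth 0.0640, 0.0691, 0.0330 and 0.0282 CPM in the kidney donor, SILP donor, 2-week and 8-week libraries.

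The position of a recipient library was computed for each gene 2-fold apart between the donor libraries, as log2(recipient/kidney donor) divided by log2(SILP donor/kidney donor), so that 0 is the kidney donor level and 1 the SILP donor level. Genes at 0.75 or above were counted at the SILP level and genes at 0.25 or below at the kidney level. Because the kidney library enters both parts of the quotient, an unchanged recipient was simulated by Poisson draws from it, and the kidney cells were also split at random into equal parts. For the placement of single cells, each cell with at least 2000 UMIs was thinned to 2000, and its log-likelihood was compared between the profiles of the donor libraries. The donor profiles were made from randomly drawn donor cells, and the held-out cells gave the error rate. Shares of cells with a UMI were also taken from cells thinned to 2000 UMIs, which 2871, 4293, 8006 and 8934 cells reached.

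A total of 20 gene lists were fixed before the data were examined. Members with at least 5 CPM in any library were used, a list is described by its median log2 ratio minus the median of all genes of the comparison, and by the percentile of its median among 10000 random lists of the same size matched on mean expression. Members are counted as higher or lower at 1.5-fold before the all-gene median is taken off, so these counts also hold the offset of the comparison. Among genes with at least 20 CPM, 403 of 5421 were higher and 759 lower at 1.5-fold in SILP donor than in kidney donor cells. Against kidney donor cells it was 628 and 665 of 5673 at 2 weeks and 461 and 1773 of 5467 at 8 weeks. At 8 against 2 weeks it was 131 and 851 of 5318. The percentile describes these libraries and is not a test between conditions. Genes named in the text followed a rule fixed beforehand. It took the 10 largest ratios per direction and comparison among genes with a UMI in at least 10% of the cells of the higher library, without mitochondrial, ribosomal protein, unnamed and antigen receptor genes. It added up to 4 members per list with the largest absolute ratio, a fixed set (Il13, Il7r, Ptprc, Ccr9, Il1rl1, Il17rb, Klrg1, Il5, Areg, Gata3, Rag2, Il2rg), and for the position the 10 genes with the largest donor difference per direction at the SILP level and at the kidney level at 8 weeks.

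The computations were tested on simulated data with 200 genes of the kidney donor library given known folds. For the donor comparison, 50 of 50 genes planted 4-fold higher and 49 of 49 planted 4-fold lower were recovered among 5269 genes, and 0 of 5070 unchanged genes were counted. The simulated counts were Poisson draws, so they cannot show how many genes the spread between cells, mice or preparations would move. The median position of a recipient simulated midway between the donors was 0.516 for SILP-higher and 0.487 for kidney-higher genes. Alternatives fixed beforehand were edgeR 4.0.16 TMM factors, DESeq2 1.42.0 size factors, other cell and gene filters, pseudocounts, fold limits, thinning, and leaving out gene classes or cycling cells. A further 4 were added after the data were seen: leaving out cells with a UMI of Hspa1a, Hspa1b or Dnajb1, receptor segments, cells with a UMI of H2-Aa or Cd74, and cells over 2 times the median UMIs of their library.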

Results

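Transcripts were counted in single ILC2s from 4 libraries, 1 per group, so that no difference given here has a replicate check. Intervals cover counting error only, except those on median positions, which are taken over genes. The series title concerns the adaptation of effector ILC2s to the intestine and retinoic acid. The analysed cells held 15629417 UMIs in the kidney donor library, 14479402 in the SILP donor library, 30317753 at 2 weeks and 35493286 at 8 weeks after transfer. The median cell had 1851, 2212, 2999 and 3578 UMIs in the same order. Ribosomal protein genes took 23.4%, 25.7%, 26.3% and 33.0% of UMIs. Gata3, the transcription factor that defines ILC2s, stood at 1179 (95% interval 1162 to 1196), 951 (95% interval 935 to 967), 1061 (95% interval 1049 to 1072) and 919 (95% interval 909 to 929) CPM. Against the kidney donor library, the fixed ILC2 core list had relative medians of -0.13 in SILP donor cells (2 of 15 members higher, 3 lower) and -0.47 at 2 weeks (1 higher, 6 lower). At 8 weeks it was -0.23 (1 higher, 8 lower), where 461 of 5467 genes were higher and 1773 lower at 1.5-fold. The gate genes Il7r and Ptprc stood at 477 and 368 CPM in the kidney donor library, 594 and 281 in the SILP donor library, 232 and 264 at 2 weeks and 316 and 249 at 8 weeks. Rag2, inactivated in the recipients and not used by mature ILC2s, had 0 UMIs in every library, which allows up to 0.207 CPM in the shallowest. Il2rg, inactivated in the recipients, was present at 274 CPM at 2 weeks and 297 CPM at 8 weeks beside 281 CPM in the kidney donor library. Cells named as other types made up 0.111%, 1.38%, 0.0747% and 0.808% of retained cells and were left out.

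The donor libraries compare ILC2s of kidney and small intestine after IL-33. Gzma, which encodes the protease granzyme A, was near absent in kidney cells, with 3 UMIs, and reached 476 (95% interval 465 to 488) CPM in SILP cells (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981). Art2b, an ADP-ribosyltransferase gene, had 0 UMIs in kidney cells and was at least 655-fold higher in SILP cells (ENSMUSG00000030651, chromosome 7, 101576970 to 101585600). Cd160, an immunoglobulin-family receptor gene, was 310.0-fold higher (133 to 956), Ret, a receptor tyrosine kinase gene, 189-fold higher (99.4 to 415), and the natural killer granule gene Nkg7 51.8-fold higher (37.3 to 74.2) in SILP cells. In the other direction, Sema4a was 39.1-fold lower (30.4 to 51.1), Stab2 13.9-fold lower (12.4 to 15.7), S100a4 11.5-fold lower (10.8 to 12.3) and Alox5ap, needed for leukotriene synthesis, 26.6-fold lower (18.5 to 39.7) in SILP cells.

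Of 5421 genes, 209 were at least 2-fold higher and 226 at least 2-fold lower in the SILP donor library, beside 0 and 9 genes between random equal parts of the kidney and SILP donor cells. The median log2 ratio of all genes was -0.18, and list medians here are given relative to it. With TMM factors the split was 273 higher and 146 lower, and with DESeq2 size factors 286 higher and 138 lower. The list of NF-kB response genes had a relative median of 0.84 (percentile 100), with 11 of 19 members higher and 0 lower in SILP cells: Bcl2a1d, whose reads cannot be told with certainty from those of its paralogs, was 6.29-fold higher (5.49 to 7.24) and Tnfaip3 3.99-fold higher (3.87 to 4.11). The list of inhibitory and regulatory receptors also holds the intracellular inhibitors Cblb, Socs1, Socs2 and Cish. It had a relative median of 0.94 (7 of 13 higher), led by Cd160 and by Socs2, a feedback inhibitor of cytokine signalling, which was 21.1-fold higher (18.2 to 24.7). In the aryl hydrocarbon receptor list, 5 of 7 members were higher, with Tiparp 3.47-fold higher (3.25 to 3.71), and the transcription factor gene Hes1 stood at 4323 against 247 CPM.

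Retinoic acid response genes had a relative median of 0.35 (percentile 99.4), with 4 of 12 members higher and 2 lower in SILP cells. Hic1, a transcriptional repressor induced by retinoic acid (ENSMUSG00000043099, chromosome 11, 75164565 to 75169519), was 36.2-fold higher (25.5 to 53.2) and Dhrs3, a retinaldehyde reductase, 20.9-fold higher (12.4 to 37.8). Ccr9, the receptor for the gut chemokine CCL25, was 1.52-fold higher (1.42 to 1.62), while the retinoic acid receptor gene Rarg was 5.76-fold lower (4.81 to 6.95). Secreted factors had a relative median of -0.42: Il5 was 1.67-fold lower (1.59 to 1.75), Areg stood at 1335 against 2032 CPM and the gate gene Il13 was 1.53-fold lower (1.48 to 1.59) in SILP cells, and Il4 3.24-fold higher (3.05 to 3.43). Over the settings the log2 ratio ranged from -1.37 to -0.23 for Il5, from -1.05 to -0.20 for Areg and from -1.14 to -0.14 for Il13. Their direction held, but the size of the difference depends on the setting. Il1rl1, the IL-33 receptor, was 2.51-fold lower (2.40 to 2.63), and Klrg1 was 1.40-fold higher (1.36 to 1.44). The heat shock genes Hspa1a and Hspa1b stood at 30.5 against 1524 CPM and 5.59 against 194 CPM in SILP and kidney cells, and the tissues also differed in how cells were isolated. The list of immediate early and heat shock genes had a relative median of 0.37, with 10 of its 25 members higher in SILP cells and 5 lower. Markers of B and plasma cells summed to 4074 CPM in the SILP donor library against 47.2 CPM in the kidney donor library, 3464 CPM of the first sum being Igkc, and a single SILP donor cell held 13500 of 50162 Igkc UMIs, with 85.3% of them in 37 cells of 1 cluster. Glycolysis and oxidative phosphorylation genes had relative medians of 0.00 and -0.10.

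**Figure D1:**
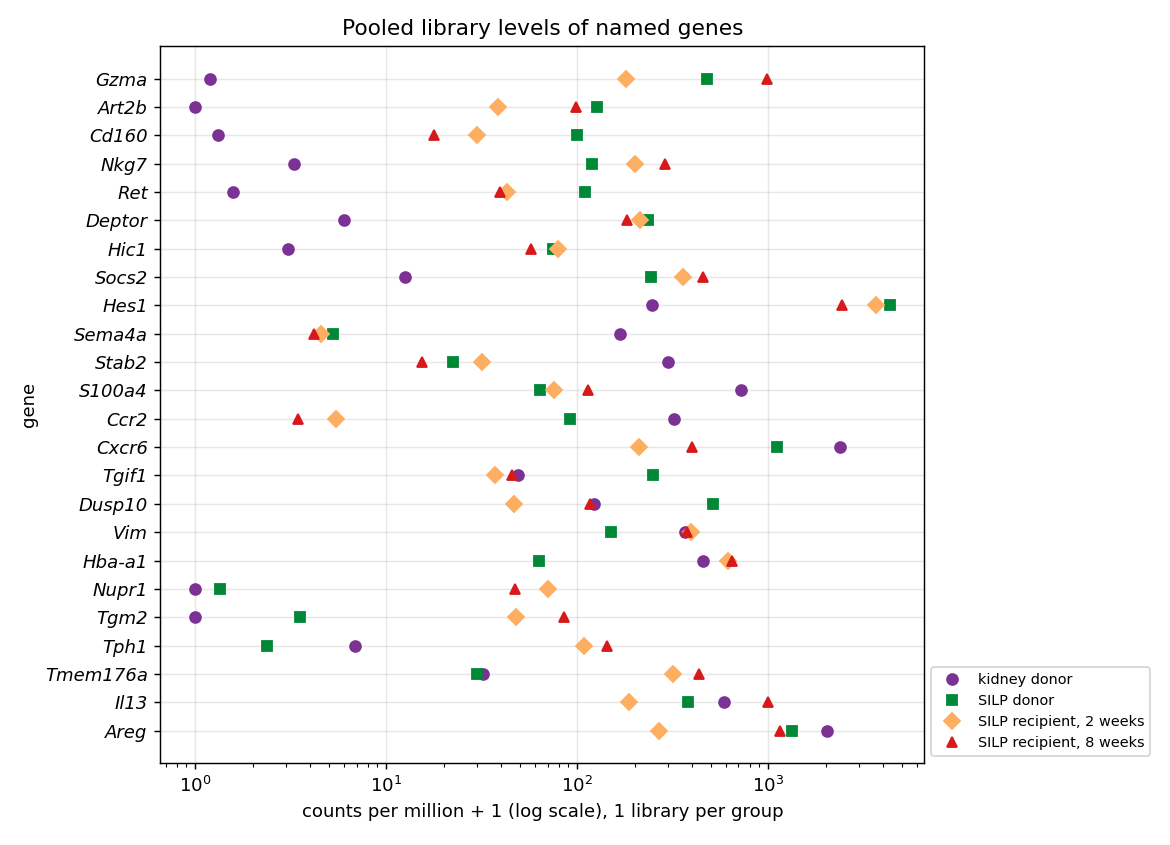
Levels of genes named by the rule in the pooled cells of each library, as CPM plus 1 on a log axis, with 1 point per library. Gzma lies at 476 CPM in the SILP donor and 982 CPM in the 8-week recipient library and near 0 in the kidney donor library, while Tgif1 of the 8-week recipient library lies at 44.7 CPM, near the kidney donor point.

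Kidney ILC2s recovered from the recipient intestine after 2 weeks were compared with the kidney donor library to ask which transcripts differed after transfer to the small intestine. Gzma stood at 179 (95% interval 174 to 183) CPM, Nkg7 was 86.6-fold higher (62.5 to 124) than in kidney donor cells and Art2b at least 194-fold higher. Hes1 was 14.8-fold higher (14.3 to 15.3) and Hic1 38.5-fold higher (27.2 to 56.4). Ccr2, a chemokine receptor gene (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557), was 71.7-fold lower (60.4 to 85.7), at 4.45 against 319 CPM. Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, was 7.62-fold lower (7.44 to 7.81), Il5 4.20-fold lower (3.99 to 4.42) and Il13 3.16-fold lower (3.05 to 3.26).

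In all, 305 of 5673 genes were at least 2-fold higher and 275 lower than in the kidney donor library, with an all-gene median of -0.03. Cell cycle genes had a relative median of 1.88 (percentile 100), and 20 of 26 members were higher and 1 lower: Mki67 stood at 19.6 against 1.28 CPM and Birc5 was 97.9-fold higher (38.1 to 360.4). In cells thinned to 2000 UMIs, a UMI of Mki67, Top2a, Cdk1 or Birc5 was seen in 8.89% (8.28 to 9.54) of 2-week cells and 3.07% (2.47 to 3.76) of kidney donor cells (12.1% and 3.49% without thinning). The macrophage gene Lyz2, which ILC2s should lack, was seen in 0.0125% and 0.0697% of the same cells. Without thinning, 284 kidney donor cells had a UMI of these cell cycle genes, with Top2a in 221, Mki67 in 20 and Birc5 in 4. A single cluster set apart by cell cycle genes held 0 kidney donor and 318 2-week cells, so the kidney share is not a share of cycling cells. Aryl hydrocarbon receptor genes had a relative median of 3.08 (6 of 7 higher), with Scin at least 114-fold higher and Ahr at 162 against 49.5 CPM. The list of inhibitory and regulatory receptors had a relative median of 2.31 (10 of 13 higher), with Lilrb4a 35.3-fold higher (29.8 to 42.3). Interferon response genes had a relative median of 1.03 (12 of 19 higher), with Igtp 3.08-fold higher (2.78 to 3.42). Homing and adhesion genes had a relative median of -0.74, with 9 of 17 members lower and 0 higher: Cxcr6 was 11.4-fold lower (11.1 to 11.7) and Ccr9 4.67-fold lower (4.27 to 5.11).

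After 8 weeks, Gzma reached 982 (95% interval 972 to 993) CPM and Nkg7 was 124-fold higher (89.7 to 178) than in kidney donor cells. Among cells thinned to 2000 UMIs, Gzma was seen in 18.4% (17.6 to 19.2) at 8 weeks, 3.52% (3.13 to 3.95) at 2 weeks, 11.9% (11.0 to 12.9) of SILP donor cells and 0 of 2871 kidney donor cells, which allows up to 0.104% (23.7%, 4.03%, 11.3% and 0.0123% without thinning). The plasma cell transcript Igkc, which ILC2s should lack, was seen in 12.4% of the same SILP donor cells, so there the share alone does not show that ILC2s held Gzma. Without thinning, SILP donor cells with a UMI of Gzma had a median of 4 of them, and those with a UMI of Igkc a median of 1. A single cluster held 65.2% of Gzma UMIs at 8 weeks (1740 of 9202 cells) and 56.5% at 2 weeks (411 of 9363 cells). In the SILP donor library it held 1.52% (34 of 6210 cells). Clusters largely followed the libraries, so a similar subset of SILP donor cells is not excluded. Socs2 was 39.6-fold higher (34.2 to 46.1), Hes1 9.87-fold higher (9.55 to 10.2) and Hic1 27.4-fold higher (19.3 to 40.2). The gate gene Il13 was 1.71-fold higher (1.67 to 1.75), while Areg was 1.76-fold lower (1.74 to 1.79), Il5 1.85-fold lower (1.78 to 1.92) and Il1rl1 4.60-fold lower (4.42 to 4.79). Over the settings the log2 ratio ranged from 0.24 to 1.17 for Il13, from -1.30 to -0.42 for Areg and from -1.44 to -0.43 for Il5. Ccr2 was 130.3-fold lower (105 to 163) and Sema4a 52.1-fold lower (43.2 to 63.4).

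In this comparison 253 of 5467 genes were at least 2-fold higher and 617 lower, and the all-gene median was -0.37. The split depended on the scaling: it was 455 higher and 243 lower with TMM factors and 369 higher and 434 lower without mitochondrial and ribosomal protein genes, with 469 higher and 240 lower under DESeq2 size factors. Relative to the all-gene median, the aryl hydrocarbon receptor list stood at 3.13 and the list of inhibitory and regulatory receptors at 2.15 (9 of 13 higher). The cell cycle list stood at 0.81 (12 of 26 higher and 5 lower), the interferon list at 0.95 (9 of 19 higher and 3 lower) and the homing and adhesion list at -0.83 (11 of 17 lower). Member counts are not relative to that median, and at 1.5-fold 461 of the 5467 genes were higher and 1773 lower. Retinoic acid response genes stood at 0.06 (percentile 66.0, 3 of 12 higher and 4 lower) at 8 weeks and at 0.24 (percentile 94.2, 3 higher and 4 lower) at 2 weeks, with Tgm2, a transglutaminase gene, at least 442-fold higher, Dhrs3 22.0-fold higher (13.3 to 39.5) and Rarg 11.6-fold lower (9.82 to 13.8) at 8 weeks.

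**Figure D2:**
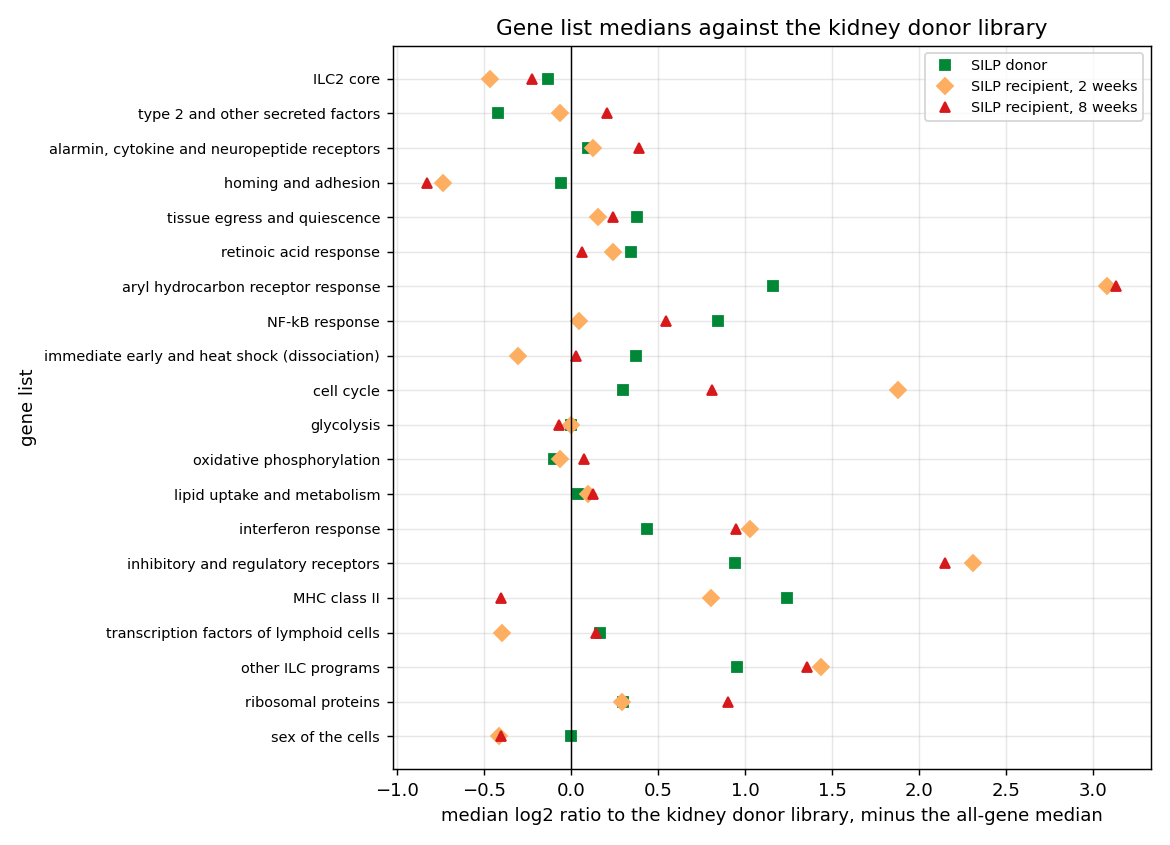
Median log2 ratio to the kidney donor library of each of the 20 fixed gene lists, minus the median of all genes, for the SILP donor and both recipient libraries, with 1 point per library. The aryl hydrocarbon receptor list lies at 1.16, 3.08 and 3.13, and the homing list at -0.06, -0.74 and -0.83 in the SILP donor, 2-week and 8-week libraries.

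Between the recipient time points, cell cycle genes were lower at 8 weeks, with a relative median of -0.95 and 24 of 26 members lower: Rrm2 was 5.55-fold lower (4.83 to 6.41) and Mki67 3.77-fold lower (3.19 to 4.48). Gzma was 5.50-fold higher (5.35 to 5.66), Il13 5.41-fold higher (5.26 to 5.57), Areg 4.32-fold higher (4.22 to 4.43) and Il5 2.28-fold higher (2.17 to 2.39) at 8 weeks. MHC class II genes had a relative median of -0.92 (4 of 5 lower), with Cd74 3.58-fold lower (3.27 to 3.92). This lay in few cells, in a single cluster set apart by Cd74 and MHC class II genes. The cluster reached the limit of 3 dendritic cell markers but was kept, since 0 ILC2 markers were low in it. It held 228 of 9363 cells and 81.4% of Cd74 UMIs at 2 weeks, and 41 of 9202 cells and 71.7% at 8 weeks. These libraries differed least of all pairs by rank correlation across genes (Spearman 0.976 over 9054 genes, which are not replicates). Only 43 of 5318 genes were 2-fold higher and 85 lower at 8 weeks, with an all-gene median of -0.31, and the split was 118 higher and 19 lower with TMM factors, 122 higher and 17 lower with DESeq2 size factors and 67 higher and 81 lower without mitochondrial and ribosomal protein genes.

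Recipient cells were then set against the resident SILP donor cells of the same tissue. At 2 weeks Ccr2 was 20.4-fold lower (17.0 to 24.5), Cxcr6 5.31-fold lower (5.15 to 5.46) and Areg 5.01-fold lower (4.88 to 5.14) than in SILP donor cells, while Creb5, a transcription factor gene, was 54.5-fold higher (35.2 to 89.4) and Tph1, the enzyme that starts serotonin synthesis, 78.4-fold higher (50.7 to 128). NF-kB response genes had a relative median of -0.84 (11 of 19 lower), with Bcl2a1d 35.4-fold lower (28.4 to 44.8), and immediate early and heat shock genes, which also respond to handling, had one of -0.55 (11 of 25 lower). At 8 weeks Ccr2 was 37.0-fold lower (29.8 to 46.5), Ccr9 3.52-fold lower (3.30 to 3.75) and Tcf7, a transcription factor of lymphoid precursors, 13.7-fold lower (10.2 to 18.6), while Tgm2 was 33.2-fold higher (24.0 to 47.3), Nupr1 135-fold higher (57.6 to 415) and Gzma 2.06-fold higher (2.01 to 2.12). The Gzma log2 ratio ranged from 0.83 to 1.24 over the settings, on both sides of 2-fold. The counts were 264 higher and 207 lower of 5478 genes at 2 weeks and 147 higher and 236 lower of 5058 at 8 weeks, with all-gene medians of 0.15 and -0.19. With TMM factors they were 169 higher and 272 lower at 2 weeks and 231 higher and 157 lower at 8 weeks, and with DESeq2 size factors 158 higher and 291 lower and 221 higher and 165 lower. Without mitochondrial and ribosomal protein genes the 8-week split was 230 higher and 199 lower.

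The position of recipient cells between the donor tissues was read from the genes that set the donor libraries apart. Among SILP-higher genes, Gzma, Art2b, Nkg7, Deptor, Hic1 and Socs2 were at the SILP level at 8 weeks, while Tgif1, Tgif2, Dusp10 and Bcl2a1d were at the kidney level: Tgif1 stood at 44.7 CPM against 48.2 in kidney and 248 in SILP donor cells. Gzma UMIs lay mostly in different clusters in the 8-week and SILP donor libraries. Clusters largely followed the libraries, with 5817 SILP donor and 13 8-week cells in a single cluster, so this cannot show that different subsets held Gzma. Among kidney-higher genes, Sema4a, Stab2 and Krt83 were at the SILP level, and Vim and the alpha-globin gene Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465) at the kidney level, with Hba-a1 at 646 CPM against 457 and 62.3. The median position of the 209 SILP-higher genes was 0.671 (0.539 to 0.719) at 2 weeks and 0.629 (0.582 to 0.767) at 8 weeks. That of the 226 kidney-higher genes was 0.780 (0.706 to 0.857) and 1.05 (0.977 to 1.15), with 95% intervals over genes, which are not replicates. With TMM factors the 8-week medians were 0.769 for SILP-higher and 0.938 for kidney-higher genes, outside these intervals, so the contrast between the sets depends in part on the scaling. At 8 weeks 93 SILP-higher genes were at the SILP level and 44 at the kidney level, and 171 kidney-higher genes were at the SILP level and 10 at the kidney level. The simulated unchanged recipient had 0 genes at the SILP level in each set. It holds counting error only, so it cannot show how many genes a difference between mice, preparations or protocols would move. With split kidney cells the 8-week medians were 0.606 and 1.03. The recipients differ from both donors in genotype and in transfer itself, and their labels give no IL-33 treatment. The kidney donor library alone was made by bead enrichment, while SILP donor and recipient cells shared an isolation protocol. A shift toward the SILP level cannot be told apart from these differences, so the position does not isolate the tissue.

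**Figure D3:**
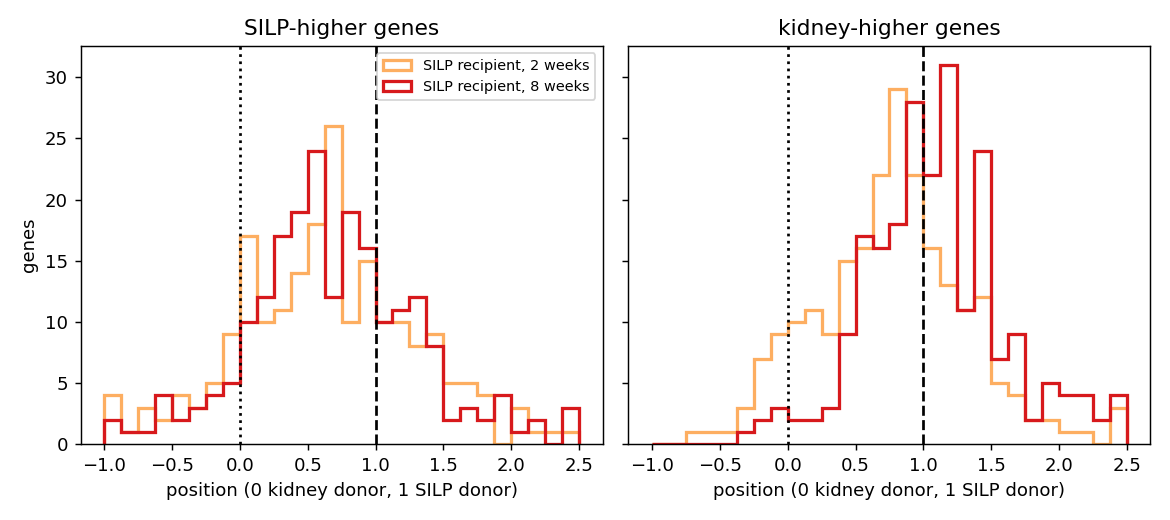
Position of each gene of the recipient libraries between the kidney donor level (0, dotted) and the SILP donor level (1, dashed), in numbers of genes, for SILP-higher and kidney-higher genes. Values past the ends of the axis are drawn in the end bins, and the 8-week kidney-higher genes centre on 1.05.

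Single cells were placed between the donor profiles to see whether recipient libraries held a mixture. Of 2-week cells, 87.0% (95% interval 86.2 to 87.7, 8006 cells) were nearer to the SILP profile, and of 8-week cells 98.0% (97.7 to 98.3, 8934 cells). Of held-out donor cells, 1.09% of kidney cells and 97.6% of SILP cells were nearer to the SILP profile. The score is a range: 8.84% of 2-week cells lay within 10 log-likelihood units of 0, and the median score was 56.1 at 2 weeks, 111 at 8 weeks and 166 in SILP donor cells. The limits given for the position, of genotype, transfer, IL-33 treatment and isolation protocol, hold for the placement too. The score also covers only what set the donor profiles apart, and does not measure how alike recipient and SILP donor cells were. Over 9054 genes the Spearman correlation with the SILP donor library was 0.936 at 2 weeks and 0.941 at 8 weeks. Between the donor libraries it was 0.934.

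**Figure D4:**
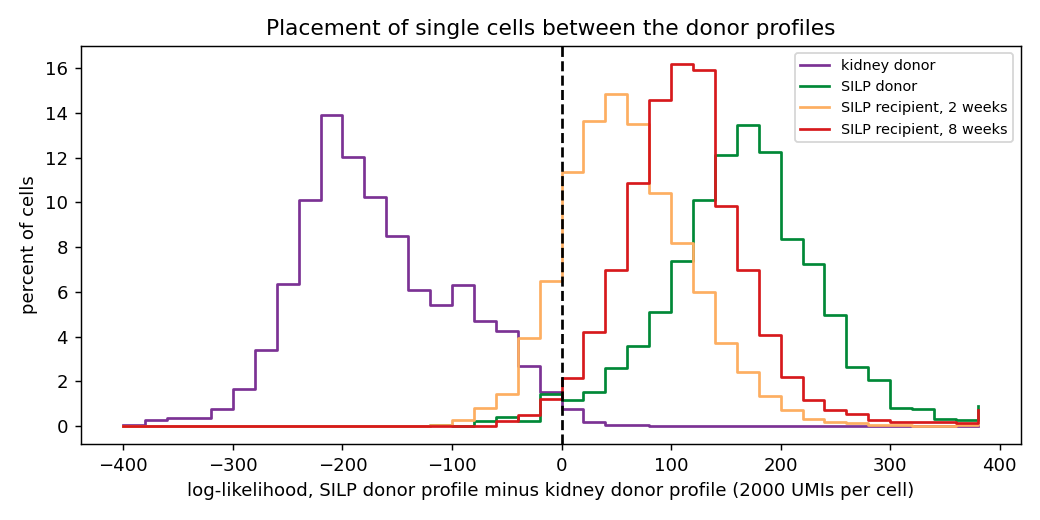
Percent of cells by the log-likelihood of their counts under the SILP donor profile minus that under the kidney donor profile, for the held-out donor cells and both recipient libraries, each cell thinned to 2000 UMIs. Both recipient libraries form a single broad peak right of 0, with medians of 56.1 and 111, left of the SILP donor median of 166. Scores past the ends are drawn in the end bins.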

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

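None of the differences given here was tested, since each group had 1 library. All log2 ratios here are to the kidney donor library, and the listed genes lay on opposite sides of its level at 2 and 8 weeks. The MHC class II list had a median of 0.77 at 2 weeks and -0.77 at 8 weeks, or 0.80 and -0.40 relative to the median of all genes. With cells thinned to 2000 UMIs the MHC class II medians were -0.13 and -1.45, and without heat shock-marked cells, a setting chosen after seeing the data, 1.55 and 0.86, so the opposite signs depend on the cells used. H2-Aa stood at 0.77 and -0.77 and Cd74 at 0.92 and -0.87. Their kidney level rests on few cells: a single kidney donor cell held 238 of 524 Cd74 UMIs and a single one 76 of 195 H2-Aa UMIs. A cluster of 16 kidney donor cells held 87.2% and 86.2% of them. Whether the 8-week level lay below that of most kidney cells therefore stays open. Tnf stood at 1.04 and -0.71, Sertad1 at 0.94 and -1.37, and the cell cycle gene Cks2 at 0.73 and -0.64. With TMM factors these were 0.78 and -0.43 for H2-Aa, 0.93 and -0.50 for Cd74, 1.05 and -0.37 for Tnf, 0.95 and -1.03 for Sertad1 and 0.74 and -0.27 for Cks2, so how far the 8-week values lay below the kidney level depends on the scaling. Il13 stood at -1.65 and 0.78, but cells were sorted on the IL-13 reporter, so this is no finding.

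A cluster left out of the comparisons was named for ILC3s by the marker rule. Its most enriched genes included Il22 and Il17a, which gamma-delta T cells share, and Jaml, Cd163l1, Gzmb and Klrk1, so its cell type stays open. Its cells made up 0.0491% of retained cells in the kidney donor library (4 cells), 1.35% in the SILP donor library (85 cells), 0.0427% at 2 weeks (4 cells) and 0.744% at 8 weeks (69 cells). At both 0.5 and 2 times the clustering resolution the shares were 0.429% in the SILP donor library (27 cells) and 0.733% at 8 weeks (68 cells), so which of these was higher depends on the clustering. A count of 0 would allow 0.0323% at 8 weeks. These are signals in cells that no comparison used.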

How the results depend on the processing

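The settings that left out heat shock-marked cells, receptor segments, MHC class II-marked cells or deep cells, and the placement without receptor segments, were chosen after seeing the data. Each count of genes 2-fold apart was recomputed under 22 alternatives and each median position under 24. No median position changed sign, while the scaling, the pseudocount, the fold limit and the limit on expression turned the higher and lower split of several comparisons. The alternative without Scrublet calls is void, since none were made. Of 120 list medians under up to 14 alternatives, 0 passed from one end of the random lists to the other, 52 values passed between an end and the middle and 1622 did neither. Of 73 log2 ratios of named genes, 23 changed side of the fold limit under some alternative, the other fold limits included, and 0 values reversed.

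Counts are given in the order SILP donor against kidney donor, 2 weeks against kidney, 8 weeks against kidney, 8 against 2 weeks, 2 weeks against SILP donor and 8 weeks against SILP donor. They follow from the limits by construction: 817, 973, 1495, 297, 839 and 662 at 5 CPM, 164, 203, 265, 28, 161 and 137 at 100 CPM, 1119, 1338, 1891, 391, 1142 and 874 with no filter on low genes, 1162, 1293, 2234, 982, 1247 and 1194 at 1.5-fold and 134, 173, 202, 9, 95 and 73 at 4-fold. With a pseudocount of 5 CPM, 77 genes differed between 8 and 2 weeks. Of genes 2-fold apart between 8 weeks and kidney, 54.0% were lower without mitochondrial and ribosomal protein genes. The share was 34.8% with TMM factors, so the scaling changed the surplus. After thinning it was 68.8%, but thinning keeps each gene's expected share of a cell's UMIs, so this cannot decide whether cell depth accounted for the surplus.

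Beside the splits under TMM and DESeq2 factors given with the comparisons, which side held more genes also turned under the settings that follow, and the cause was not tested. Between the donors it was 260 higher and 235 lower in SILP cells without mitochondrial and ribosomal protein genes, 178 higher and 167 lower with a pseudocount of 5 CPM, 92 higher and 72 lower at 100 CPM and 81 higher and 53 lower at 4-fold. At 2 weeks against kidney it was 101 higher and 102 lower at 100 CPM and 628 higher and 665 lower at 1.5-fold, and at 8 weeks against kidney 115 higher and 87 lower at 4-fold. At 8 against 2 weeks it was 23 higher and 5 lower at 100 CPM and 6 higher and 3 lower at 4-fold. Against SILP donor cells it was 60 higher and 101 lower at 100 CPM at 2 weeks, and 44 higher and 29 lower at 4-fold at 8 weeks, where the split without mitochondrial and ribosomal protein genes also turned.

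The cause was not tested for the values that follow. The median position of kidney-higher genes at 2 weeks was 0.873 for genes seen in at least 10% of cells, 0.890 with TMM, 0.917 with DESeq2 factors, 0.700 without mitochondrial and ribosomal protein genes, 0.679 with the stricter cell filter, 0.682 after thinning and 0.903 without heat shock-marked cells. It was 0.672 at 5 CPM, 0.938 at 100 CPM, 0.667 with no filter and 0.621 at 1.5-fold. At 8 weeks it was 0.938 with TMM, 0.951 with DESeq2 factors, 0.934 without mitochondrial and ribosomal protein genes, 0.967 after thinning, 0.968 with no filter and 0.940 at 4-fold. That of SILP-higher genes at 8 weeks was 0.769 with TMM, 0.549 at 1.5-fold and 0.826 at 4-fold.

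The share of cells nearer to the SILP profile at 2 and 8 weeks was 84.6% and 97.6% at 1000 UMIs per cell, and 85.7% and 98.5% at 4000. It was 81.3% and 95.7% without immediate early, heat shock, ribosomal protein and mitochondrial genes, and 88.5% and 98.7% without receptor segments. With only genes at most 4-fold apart between donors it was 81.3% at 2 weeks. Cells of other types in the SILP donor library came to 0.461% at both 0.5 and 2 times the clustering resolution.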

Other observations

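Some genes set transferred cells apart from both donor tissues at once. At least 2-fold higher in both recipient libraries than in both donor libraries were 79 genes, and 39 were at least 2-fold lower (86 and 27 with TMM factors, 75 and 21 of them shared). The stress response gene Nupr1 stood at 69.1 and 46.5 CPM in the recipients at 2 and 8 weeks and at 0 and 0.345 CPM in the kidney and SILP donor libraries. Cyp11a1, the first enzyme of steroid hormone synthesis, stood at 91.3 and 49.95 against 1.41 and 0.345 CPM, Tph1 at 108 and 143 against 5.89 and 1.38, and Il6 at 108 and 178 against 4.09 and 21.4. Rxrg, a retinoid X receptor gene, stood at 159 and 101 against 3.14 and 47.9 CPM. Lower genes included Ccr2, Cxcr6, Ccr9 and Calca, the last at 234 and 284 against 1326 and 821 CPM.

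The T cell receptor gamma constant gene Tcrg-C1, outside the rule for named genes and chosen after its values were seen, stood at 3.01 CPM in the kidney donor library, 375 CPM in the SILP donor library, 1593 CPM at 2 weeks and 996 CPM at 8 weeks. A UMI of Tcrg-C1 was seen without thinning in 0.467%, 35.5%, 91.4% and 87.9% of cells, whose median depths were 1851, 2212, 2999 and 3578 UMIs. The immunoglobulin light chain gene Igkc, a B and plasma cell transcript, was seen in 12.4% of thinned SILP donor cells, 0.418% of kidney donor cells, 0.0125% of 2-week cells and 0 of 8934 8-week cells.

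Of the tests that follow, those of epithelial free RNA, of red cell free RNA and of tissue handling were chosen only after the result was seen. The difference of transferred cells from both donors was weighed first. Epithelial free RNA as the whole source is argued against, since at 8 weeks Epcam, Krt8, Fabp2, Apoa1 and Reg3b summed to 0.428 times the SILP donor level, and at 2 weeks, where they were higher (31.1 against 17.1 CPM), a single cell held 579 of 587 Reg3b UMIs and the sum without Reg3b was 11.7 CPM. An earlier form of this test, which set the higher recipient sum against a bound of 20 CPM, left the explanation open because the 2-week sum lay above it, and the present form replaced it after both values were seen. Cycling cells are argued against too, since 99.2% of the genes kept their difference without cells that had a UMI of Mki67, Top2a, Cdk1 or Birc5. Free RNA of other cell types, the recipients' genotype, transfer itself and the absence of IL-33 treatment from the recipients' labels stay open, and were not tested.

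Alpha-globin UMIs were found with many analysed cells: Hba-a1 had a UMI in 38.6% (36.8 to 40.4) of thinned kidney donor cells, 10.2% (9.29 to 11.1) of SILP donor cells, 56.0% (54.9 to 57.0) of 2-week cells and 60.6% (59.6 to 61.7) of 8-week cells (34.0%, 10.2%, 63.7% and 74.0% without thinning). For comparison, the macrophage gene Lyz2 had a UMI in 0.0697%, 0.0932%, 0.0125% and 0.0448% of thinned cells. Free RNA from red blood cells would bring beta-globin, which had 0 UMIs per 100 alpha-globin UMIs at 8 weeks (at most 0.0149 by counting error) and 5.37 in the SILP donor library. A few red cells or doublets are argued against for the 8-week library, since the 1% of its cells with most alpha-globin held 6.48% of its UMIs. That share was 7.40% at 2 weeks, 11.9% in the kidney donor library and 22.7% in the SILP donor library. Both donor values lie above the bound set for arguing against this source, so for the donor libraries it stays open. Expression in the ILC2s themselves and free alpha-globin RNA of another source stay open and were not tested, and reads cannot be assigned with certainty between Hba-a1 and its near-identical copy Hba-a2.

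The kidney donor library stood apart by heat shock transcripts, with a UMI of Hspa1a, Hspa1b or Dnajb1 in 63.3% (61.5 to 65.1) of thinned cells against 18.4%, 18.7% and 14.0% in the SILP donor, 2-week and 8-week libraries. Members of the immediate early and heat shock list made up 1.77% of the 226 kidney-higher genes, a share that decides nothing, since all its eligible members together would have come to 10.6%. Without cells that had such a UMI, 76.5% of the genes (173) stayed 2-fold apart, which lies between the bounds set before the value was seen, so a contribution of stressed cells stays open for the rest. Under the counting rule of the comparisons, with its limit of 20 CPM, 167 of the 226 genes were counted again. Handling and tissue cannot be told apart for Hspa1a, 50.02 times higher in kidney cells, because the kidney library alone was made by bead enrichment.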
